A study of Macaca mulatta with 16 samples.

How the data were processed

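The deposited tables hold 1 intensity per probe set and array on a linear scale, as the authors scaled them, for rhesus macaque RNA hybridised to the human array types U133A and U133B. After trimming 2% of the values at either end, the mean was between 1500.2 and 1500.7 units on every array, which is the mark of a per-array global scaling by the authors; the summary software and detection calls were not given in the sources used here. Per the labels, layer RNA was amplified with T7 polymerase after laser microdissection, and whole muscle RNA followed the standard protocol.

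Groups, tests, thresholds, gene lists and alternatives were chosen before the data were examined, except for the tests that the closing section names as chosen later. Arrays were grouped by title. On U133A, orbital layer replicate 1 carries a title that names the orbital layer and a source name that names the global layer; the title was used, and the results without that array were computed as well. The source name of U133B global layer replicate 1 names the layers without saying which. Titles number the layer arrays and 4 of the 8 rectus arrays; the other 4 were numbered in their order of deposit. Neither numbers nor labels say which arrays share an animal.

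Each array was scaled to a common 2% trimmed mean, values below the pooled 20th percentile of the table (146.487 on U133A and 218.465 on U133B) were raised to it, and log2 was taken. For each comparison, probe sets were kept when their mean over the arrays compared reached the pooled median of the table (653.942 and 802.702). The 68 control probe sets of each table were left out of all tests. The U133A and U133B tables were analysed separately. Comparisons were made with limma 3.58.1 in R 4.3.3 (moderated variances with an intensity trend, 2 groups, no other term), with Benjamini-Hochberg adjustment over the probe sets kept in a table and a threshold of adjusted p under 0.05. All tests were two-sided. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 drew the figures. As a rule that needs no model, probe sets were counted in which every array of one group lay at least 2-fold above every array of the other, and this count was repeated for the other ways of splitting the same 4 arrays into pairs.

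The 22 gene lists were tested with camera in limma, with its preset correlation between genes and with an estimated one, adjusted over the lists of a comparison and table. Each gene was represented by its probe set with the highest mean, and lists with under 5 kept members were not tested. Gene symbols came from the platform annotation. Of 22283 probe sets on U133A, 19071 carried 1 symbol, 1043 several and 2169 none; of 22645 on U133B, the numbers were 15432, 554 and 6659. Probe sets with several symbols or none were counted and not named.

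Named genes followed a fixed rule. For each comparison, up to 10 genes in each direction with the largest log2 difference among those past the threshold over both tables were taken. Empty places were filled with the genes with the largest difference among those at least 2-fold apart in all pairings of arrays, given as values that did not pass. Members of each list past the threshold, up to 4 members of each list with the smallest p, and 8 myosin heavy chain genes were added.

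The alternatives were quantile normalization, a floor at the 5th or the 40th percentile, no filter, a filter at the 75th percentile, variances without a trend, array weights, all 4 groups in one fit, replicate numbers as a term for the layers, the mean of all probe sets of a gene for the lists, and each array left out in turn. In simulated tables with the spread of these data and 200 probe sets changed, drawn 20 times, limma found 91.2% of 8-fold and 4.45% of 2-fold changes between the layers on U133A, and 5.47% of its calls were false when variances followed the fitted prior. With the moderated variances of the data in place of the prior, it found 99.2% of 8-fold and 30.7% of 2-fold changes, and 8.79% of calls were false. Between the layers on U133B, it found 62.55% of 8-fold and 1.15% of 2-fold changes with the prior. With the moderated variances, these were 86.55% and 13.4%. For medial against lateral rectus on U133A, it found 2.15% of 2-fold changes with the prior and 17.9% with the moderated variances; for layers against whole muscle it found 97.4% and 98.6% of 8-fold changes.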

Results

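The data were 16 arrays of RNA from extraocular muscle of adult rhesus macaques, the muscles that move the eye. These muscles have an outer orbital layer and an inner global layer. Both layers were taken by laser microdissection, and whole lateral rectus and whole medial rectus were sampled as well. Each of these 4 groups was measured with 2 arrays on each of 2 human array types, U133A and U133B, and this number of arrays limits the precision of every value. Per the labels, RNA of the layers was amplified with T7 polymerase, whereas RNA of whole muscle followed the standard protocol. Values are intensities as scaled per array by the authors. P-values measure only the spread between these samples, since nothing says that they came from separate animals. The labels do not tie the microdissected regions to animals, so p-values between layers may be too small.

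Some RNA measures moved with the groups. The ratio of 3' to 5' signal of ACTB, the beta-actin gene, was 4.22 ± 1.59 (SD, n = 4) in the layers and 0.870 ± 0.136 in whole muscle on U133A, and 4.22 ± 0.822 and 0.754 ± 0.188 on U133B. Within the layers it was 5.30 and 5.87 on the orbital arrays and 2.84 and 2.88 on the global arrays of U133A. On U133B it was 5.29 and 4.43 on the orbital arrays and 3.54 and 3.61 on the global arrays. The same ratio of GAPDH did not part the layers: it was 1.73 and 2.00 on orbital and 2.92 and 1.497 on global arrays of U133A, and 2.49 and 3.74 against 4.33 and 2.04 on U133B. In whole muscle the GAPDH ratio was 0.947 to 1.66 on U133A, which overlaps the layers, and 1.18 to 1.74 on U133B, which lies below them. Median intensity on U133A was 525 ± 46.3 in the layers and 814 ± 27.4 in whole muscle.

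**Figure D1:**
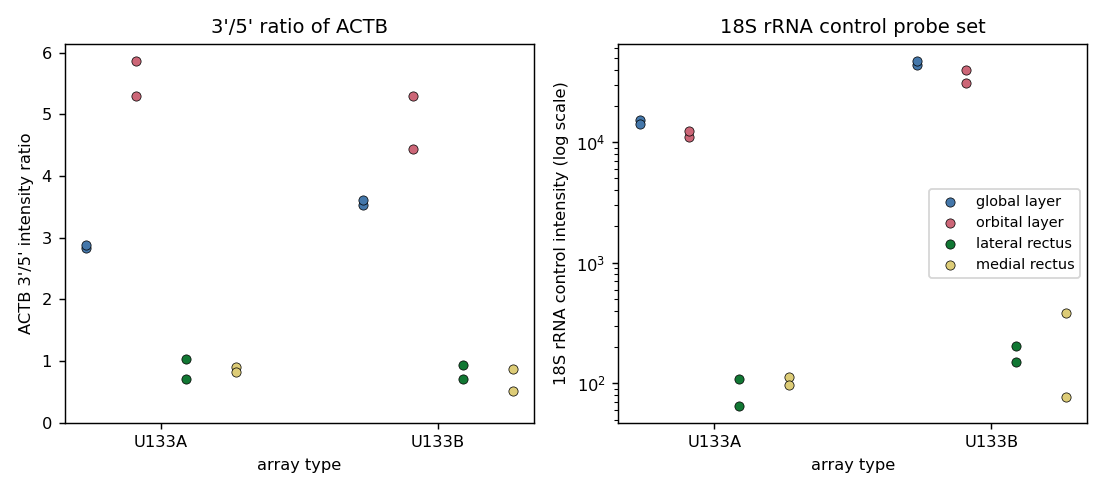
ACTB 3'/5' intensity ratio (left) and intensity of the 18S ribosomal RNA control probe set (right, log scale) for each array (points) of the 4 groups on U133A and U133B. Ratios lie between 2.84 and 5.87 on layer arrays and the 18S control averages 13191 on layer arrays and 96.1 on whole muscle arrays of U133A.

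Orbital and global layers were compared to find which genes differ between the layers of these muscles. The orbital layer had more MYH3, the embryonic myosin heavy chain, at 81824 ± 4899 intensity units against 7048 ± 5603 in the global layer (SD, n = 2 each), 14.0-fold higher (log2 difference 3.81 ± 0.51 SE, adjusted p = 0.0310 in limma). MYH6, the alpha-cardiac myosin heavy chain, was 4.35-fold higher (42682 ± 7747 against 9748 ± 757, adjusted p = 0.0154). The global layer had more ACTN3, the alpha-actinin of fast fibre Z-discs, at 23879 ± 17598 against 509 ± 242 in the orbital layer, 42.5-fold lower in the orbital layer (log2 difference −5.41 ± 0.55, adjusted p = 0.0106). CA3, a carbonic anhydrase of muscle, was 30.7-fold lower in the orbital layer (1537 ± 1388 against 37282 ± 11796, adjusted p = 0.0286). For each of these 4 genes, both arrays of one layer lay beyond both arrays of the other.

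Other genes higher in the orbital layer were PDC (phosducin, known from photoreceptors; log2 difference 3.74 ± 0.31), FZD5 (a Wnt receptor; 3.44 ± 0.47), CSRP3 (the muscle LIM protein of the Z-disc; 3.07 ± 0.31) and MYL10 (a myosin light chain; 2.83 ± 0.25). They also included ALDH1A1 (a retinaldehyde dehydrogenase; 2.83 ± 0.36), ST6GALNAC5 (a sialyltransferase; 2.74 ± 0.35), RETREG1 (a receptor for autophagy of the endoplasmic reticulum; 2.35 ± 0.24), NDP (norrin, a secreted ligand; 2.33 ± 0.30) and PDLIM4 (2.23 ± 0.28). Their adjusted p-values in limma lay between 0.00640 for PDC and 0.0361 for FZD5. SLC1A2, a glutamate transporter best known from astrocytes, was at 392 ± 245 in the orbital layer against 16734 ± 8142 on U133B, a log2 difference of −5.48 ± 0.52. CSMD1 on U133B was lower as well (−2.71 ± 0.27). On U133A, SPP1 (osteopontin; −3.37 ± 0.50), CSPG5 (a neural proteoglycan; −2.59 ± 0.26), CA2 (a carbonic anhydrase; −2.53 ± 0.38), AQP1 (a water channel of capillary endothelium; −1.94 ± 0.26), ASPH (−1.92 ± 0.24) and ATP2B2 (a calcium pump of the plasma membrane; −1.87 ± 0.27) were lower. Their adjusted p-values lay between 0.0106 and 0.0462. One orbital array of SLC1A2 and of SPP1 was at the floor, so that their differences depend on it. On the other array type, SLC1A2 (−2.51 ± 0.39) and ATP2B2 (−4.32 ± 0.52) differed the same way without passing, ST6GALNAC5 differed by 0.26 ± 0.59, and the 3 probe sets of ASPH differed by −0.66 to 0.00.

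**Figure D2:**
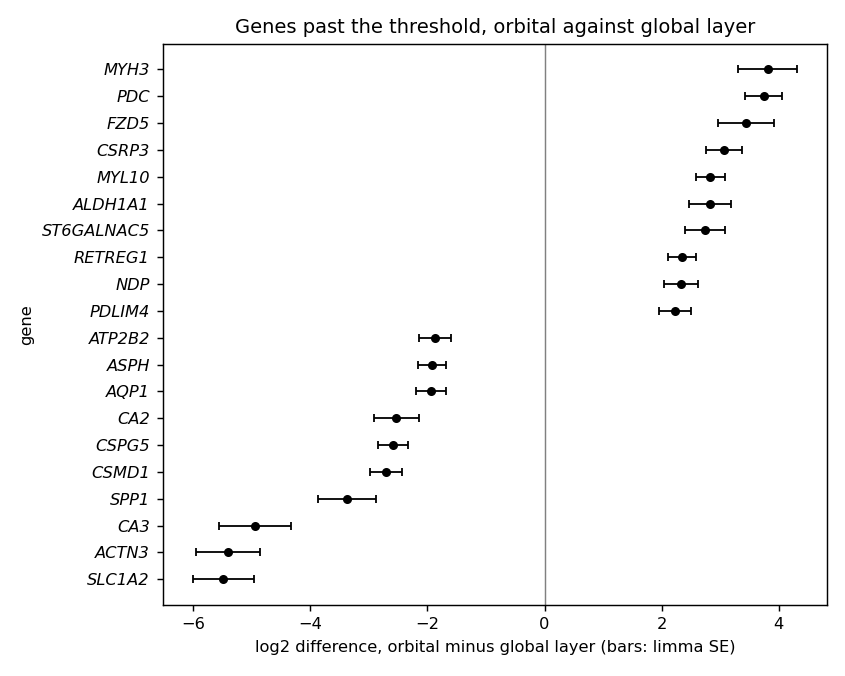
Log2 difference in intensity, orbital minus global layer (points, with limma standard errors as bars), for the 20 named genes past the threshold, 2 arrays per layer. The values run from −5.48 for SLC1A2 to 3.81 for MYH3.

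Slow fibre contractile genes were higher in the orbital layer in 14 of 14 measured members on U133A, with a median log2 difference of 0.76. Of these, 2 rose, MYH6 and CSRP3, 12 did not pass, and 7 rose when adjusted over the list alone. The camera test of the list gave adjusted p = 1.1e-09, and adjusted p = 0.517 with an estimated correlation. CASQ2, the cardiac calsequestrin, was higher by 1.42 ± 0.30 (adjusted p = 0.161 in limma). MYH7, the slow beta-cardiac myosin heavy chain, differed by 0.15 ± 0.27 (8777 against 7991). Fast fibre contractile genes were lower in 11 of 13 members, with a median of −0.32; ACTN3 fell and 12 did not pass, while 1 rose and 6 fell when adjusted over the list alone. That list had camera adjusted p = 2.9e-04, and adjusted p = 0.517 with an estimated correlation. PVALB, the calcium buffer parvalbumin, differed by −1.41 ± 0.38 (adjusted p = 0.303 in limma). Developmental and cardiac isoforms, a list that shares MYH6 with the slow one, were higher in 6 of 10 members, with a median of 0.55; MYH3 and MYH6 rose and 5 rose when adjusted over the list alone. For this list camera gave adjusted p = 8.0e-04, and adjusted p = 0.517 with an estimated correlation. MYL4, an embryonic and atrial light chain, was higher by 1.41 ± 0.26 (adjusted p = 0.0977 in limma) on its brightest probe set; its 3 other probe sets went the same way, and 2 of them passed. Of the RNA measures given above, the ACTB 3'/5' ratio was also higher on the orbital arrays, and the GAPDH ratio overlapped between the layers.

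None of the other 6 myosin heavy chain genes passed in the layers. MYH1 and MYH4, fast isoforms, were at 13336 and 76878 in the orbital layer against 32058 and 116294 in the global layer (log2 differences −1.22 ± 0.27 and −0.59 ± 0.18). MYH13, the extraocular isoform, was at 84468 against 121708 (−0.53 ± 0.18). MYH2, a fast oxidative isoform, was at 128965 against 75629 (0.80 ± 0.22), and MYH8, the perinatal isoform, at 50411 against 44705 (0.18 ± 0.20). These genes are close in sequence, and human probes may bind more than one macaque transcript.

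**Figure D3:**
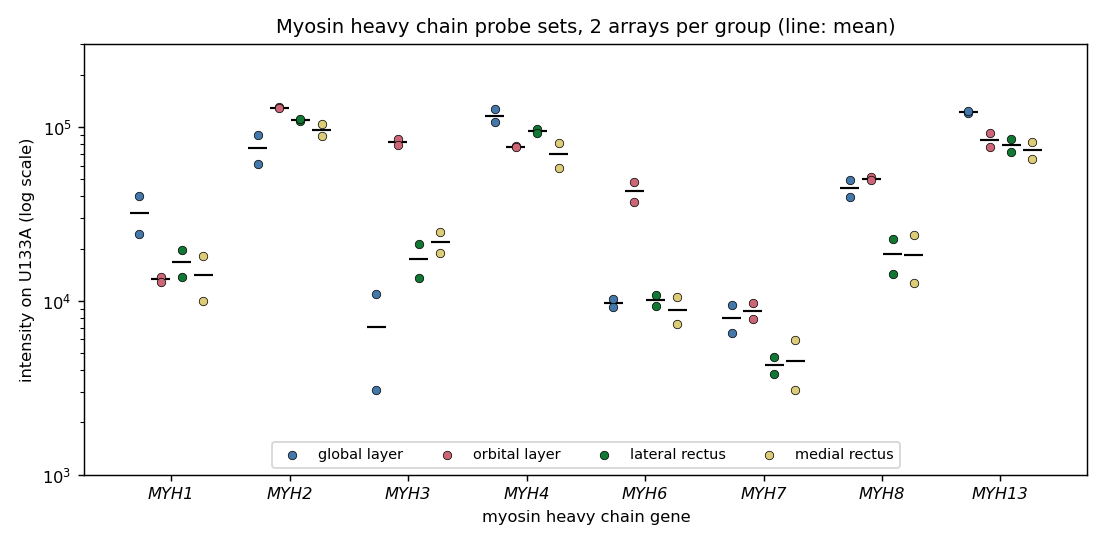
Intensity on U133A (log scale) of 8 myosin heavy chain genes on each array (points; lines are means) of the 4 groups, 2 arrays per group. The orbital layer stands apart for MYH3, at a mean of 81824, and for MYH6, at 42682.

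Among other muscle genes, glycolysis and glycogen genes were lower in the orbital layer in 17 of 23 members on U133A (median −0.33); none passed over all probe sets and 4 fell when adjusted over the list alone. Its camera adjusted p was 0.00851, and adjusted p = 0.573 with an estimated correlation. FBP2, LDHA and PHKA1 differed by −1.33, −0.97 and −0.92. In excitation-contraction coupling, SLN, an inhibitor of the sarcoplasmic calcium pump, rose by 1.86 ± 0.23 (35846 ± 5112 against 9882 ± 1070) and ASPH fell, 13 did not pass, and 3 rose and 3 fell when adjusted over the list alone (median −0.10, camera adjusted p = 0.662). On U133B, 5 of 7 members of that list were lower (median −0.66), 2 fell when adjusted over the list alone, and camera gave adjusted p = 0.0149 and adjusted p = 0.558 with an estimated correlation. Oxidative phosphorylation genes were lower in 45 of 65 members on U133A (median −0.12, camera adjusted p = 0.111, and adjusted p = 0.573 with an estimated correlation), and none passed. With the preset correlation alone, the list passed under quantile normalization (−0.16, adjusted p = 0.0108) and without global layer replicate 1 (−0.24, adjusted p = 0.00177; range over its alternatives 0.00177 to 0.933). TCA cycle genes (median −0.11), fatty acid genes (−0.13), sarcomere genes (−0.03) and dystrophin complex genes (0.27) had camera adjusted p above 0.05, and none of their members passed on U133A.

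Lists of markers of other cells were compared between the layers as well. Extracellular matrix and fibroblast genes were higher in the orbital layer in 20 of 28 members (median 0.16), with COL3A1 at 0.97 ± 0.22 on U133A and −0.03 ± 0.29 on U133B and none past the threshold, also when adjusted over the list alone. The list's camera adjusted p was 0.00621, and adjusted p = 0.573 with an estimated correlation. Pericyte and smooth muscle genes were higher in 7 of 9 members (median 0.16), with 2 rising when adjusted over the list alone; MYLK, a myosin light chain kinase, was higher by 1.25 ± 0.25 on U133A and by 0.15 ± 0.25 on U133B. That list had camera adjusted p = 0.00851, and adjusted p = 0.517 with an estimated correlation. Immediate early and stress genes were higher in 14 of 15 members (median 0.31, camera adjusted p = 0.0131, and adjusted p = 0.517 with an estimated correlation), with ATF3 at 0.77 and none past the threshold. Endothelial genes were lower in 11 of 14 members on U133A (median −0.19, camera adjusted p = 0.111), where AQP1 fell and 2 fell when adjusted over the list alone, and higher in 4 of 6 members on U133B (median 0.19, camera adjusted p = 0.550), where none passed. Neuromuscular junction, myogenic, immune and hypoxia genes had medians of 0.20, 0.22, 0.19 and −0.14 and camera adjusted p above 0.05. The mean of the myogenic list was −0.01, with a sign opposite to its median, and MSTN (myostatin) differed by −2.42 without passing. Lists given without an array type are from U133A. On U133B the dystrophin list had the opposite sign (−0.21), the matrix, myogenic and oxidative phosphorylation lists the same sign (0.13, 0.22 and −0.15), and the sarcomere list a median of 0.01 with a mean of −0.44; none of these had a camera adjusted p under 0.05. Tendon, red blood cell, adipocyte and Schwann cell lists had too few members to test in the layers.

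In total, 39 of 9532 probe sets passed in limma on U133A, 27 higher and 12 lower in the orbital layer, and 905 had an unadjusted p under 0.05, where 476.6 would be expected by chance. On U133B, 2 of 9510 passed, both lower, and 738 had an unadjusted p under 0.05. By size alone, 97 probe sets on U133A were at least 2-fold apart in all 4 pairings, against 41 when the same arrays were split by replicate number and 6 for the remaining split. On U133B they were 116, against 105 and 40, so that the split by number gave nearly as many as the layers. Counts moved with single arrays: on U133A 77 and 144 passed without global layer replicates 1 and 2, and 75 and 68 without orbital layer replicates 1 and 2, of which 32 to 36 were among the 39; none passed in limma with no filter (1607 with an unadjusted p under 0.05). Orbital layer replicate 1 is the array with conflicting labels; without it the extracellular matrix list had a median of −0.01 and adjusted p = 0.543 (range over its alternatives 7.1e-06 to 0.543).

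Calls of named genes and lists also ended under alternatives. With variances fitted without a trend 12 probe sets passed on U133A, and MYH3 and CA3 had adjusted p = 0.0664 and MYH6 0.0645 in limma (ranges over their alternatives 1.5e-09 to 0.544, 3.6e-15 to 0.532 and 2.4e-04 to 0.281). Quantile normalization ended the calls of SLC1A2, CSMD1, SPP1, CA2, FZD5 and ATP2B2, at adjusted p from 0.0510 to 0.120. ATP2B2 without global layer replicate 2 had adjusted p = 0.0543 in limma (range over its alternatives 0.0123 to 0.250). CSMD1 had adjusted p = 0.284 and 0.134 without orbital layer replicates 1 and 2 (range 0.00954 to 0.459), and SLC1A2 had 0.0924 without orbital layer replicate 2 (range 4.98e-04 to 0.516). Without global layer replicate 2, the glycolysis list had a median of −0.20 and the excitation-contraction list on U133B one of −0.04, and neither passed; without orbital layer replicate 1 neither passed at −0.37 and −0.67. The stress list did not pass without global layer replicate 1 (0.23) or orbital layer replicate 2 (0.26). With no filter the glycolysis list and the U133B list did not pass, nor did the stress list with a filter at the 75th percentile. With the preset correlation, some lists passed under alternatives alone. On U133A these were the TCA cycle list without global layer replicate 1 (−0.20), the dystrophin list without global layer replicate 2 (0.18) and the endothelial list with a filter at the 75th percentile (−0.56). On U133B they were the oxidative phosphorylation and sarcomere lists without global layer replicate 1 (−0.18 and −0.24) and with a filter at the 75th percentile (−0.38 and 0.00), and the sarcomere list with all 4 groups in one fit (0.01). The slow, fast, developmental and pericyte lists passed with the preset correlation in all alternatives tried. These alternatives reuse the same layer arrays, and none of these lists passed in camera with an estimated correlation in the main fit (adjusted p = 0.517). A second list test in limma, fry, gave them unadjusted p = 0.102, 0.0951, 0.0148 and 0.0158, in that order.

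Medial and lateral rectus, muscles that turn the eye inward and outward, were compared as whole muscles. None of 11907 probe sets on U133A and 11836 on U133B passed in limma. An unadjusted p under 0.05 was found for 333 and 406, where 595.35 and 591.8 would be expected by chance. In simulated tables with prior variances, limma found 60.95% (U133A) and 37.65% (U133B) of 8-fold changes, and 2.15% and 0.15% of 2-fold changes. With the moderated variances, it found 83.9% and 68.6% of 8-fold changes, and 17.9% and 4.75% of 2-fold changes. The absence of calls therefore does not show that the muscles are alike. HBB, the beta-globin gene of red blood cells, was lower in the medial rectus on 3 of 3 probe sets, with a median log2 difference of −1.66 and a smallest adjusted p of 0.173. S100A9 and S100A8, which together form calprotectin of neutrophils and monocytes, were at 336 ± 61.6 and 644 ± 320 in the medial and 2059 ± 291 and 2693 ± 369 in the lateral rectus (SD, n = 2), 6.16-fold and 4.44-fold apart (adjusted p = 0.736 and 0.991). PADI1, an enzyme that converts arginine to citrulline in proteins, was at 2542 ± 412 in the medial against 453 ± 165 in the lateral rectus (log2 difference 2.53 ± 0.45, adjusted p = 0.617). These 3 genes were at least 2-fold apart in all 4 pairings.

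Other genes 2-fold apart in all pairings and higher in the medial rectus were PLB1 (log2 difference 2.81 ± 0.81), NYAP2, SLAMF7 (a receptor of immune cells), MAP4K3-DT, SLC39A13 (a zinc transporter), GIMAP6, C1orf115, ST7L and LINC00626, with values from 2.31 for LINC00626 to 2.81. Lower were TRIM67 (−2.81 ± 0.64), RELCH, PYGO1, LINC01588, CADM4, RCOR2, EPN1 and ELMOD3, with values from −2.81 to −2.14; another probe set of RELCH went the opposite way. None of these passed, with adjusted p in limma of 0.991 or 0.999. On the other array type, PADI1 and SLAMF7 differed by 0.36 and 1.22, EPN1 by −0.50, ST7L by 0.14 and −0.52 on 2 probe sets, and C1orf115 (−0.97) and PYGO1 (0.46) went the opposite way. Such differences were 69 on U133A and 197 on U133B; a split of the same arrays by replicate number gave more, 138 and 354, and the remaining split 64 and 195.

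The myosin heavy chain genes differed by little between the 2 muscles, from −0.46 ± 0.22 for MYH4 to 0.35 ± 0.26 for MYH3, and all had adjusted p = 0.999 in limma; MYH13 (−0.09) and MYH8 (−0.04) changed sign under quantile normalization. Fast fibre genes were lower in the medial rectus in 12 of 13 members (median −0.21); none passed, also when adjusted over the list alone, and camera gave adjusted p = 0.0275 and adjusted p = 0.667 with an estimated correlation. On U133B, excitation-contraction coupling genes were lower in 7 of 8 members (median −0.41), again with none past the threshold, and camera gave adjusted p = 0.0384 and adjusted p = 0.864 with an estimated correlation. ATP2A2, the calcium pump of slow and cardiac muscle, differed by −1.53 in that list and by −0.27 on its brighter probe set on U133A, where another probe set went the opposite way. Oxidative phosphorylation genes were lower in 47 of 65 members on U133A (median −0.10, camera adjusted p = 0.0542), pericyte and smooth muscle genes in 8 of 8 (−0.25, 0.0889), fatty acid genes in 16 of 23 (−0.19, 0.0889) and adipocyte genes in 4 of 5 (−0.56, 0.102). All other lists tested had camera adjusted p of 0.144 or more, and the medians of the slow, developmental, sarcomere, neuromuscular junction, myogenic and matrix lists changed sign under quantile normalization. Under quantile normalization the fast list did not pass either (−0.07, adjusted p = 0.856, the highest over its alternatives), nor did it without lateral rectus replicate 1 (−0.10) or medial rectus replicate 2 (−0.11), with no filter, or with all 4 groups in one fit. Other lists passed on U133A under alternatives alone, with the preset correlation: oxidative phosphorylation without medial rectus replicate 1 (−0.16), without lateral rectus replicate 2 (−0.20) and with the mean of all probe sets of a gene (−0.09), pericyte (−0.51) and adipocyte (−0.87) genes without medial rectus replicate 1, and fatty acid genes without lateral rectus replicate 2 (−0.23). The excitation-contraction list on U133B did not pass in 8 alternatives, among them lateral rectus replicate 1 left out (−0.16, adjusted p = 0.931), replicate 2 left out (−0.55) and medial rectus replicate 2 left out (−0.12); on U133A, 9 probe sets passed without medial rectus replicate 1 and 1 without medial rectus replicate 2.

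Microdissected layers and whole muscle differed in many genes. Here tissue and protocol cannot be told apart, since layer RNA was amplified with T7 polymerase and whole muscle RNA followed the standard protocol. RTN4IP1, a mitochondrial protein, was 34.2-fold higher in the layers on U133B (8813 ± 3716 against 247 ± 56.5, SD, n = 4 each; log2 difference 5.09 ± 0.36, adjusted p = 4.9e-06 in limma), with 3 of the 4 whole muscle arrays at the floor, on which this fold depends. CXCL14, a chemokine, was 24.9-fold higher and NFIC, a transcription factor, 19.7-fold higher on U133A, while its 2 probe sets on U133B differed by 0.10 and 1.31. TRARG1, which takes part in the traffic of the glucose transporter GLUT4, was 18.3-fold lower in the layers (259 ± 47.6 against 4750.4 ± 947, adjusted p = 9.2e-06). SLC10A1, a bile acid transporter known from liver, was 12.3-fold lower and PSMD3, a proteasome subunit, 10.7-fold lower.

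Further genes higher in the layers, all on U133B, were C21orf91 (log2 difference 4.39), DMAP1 (4.35), GPAT3 (an enzyme of triglyceride synthesis; 4.05), MAP2 (a microtubule protein of neurons; 3.96), ZNF462 (3.82), ZNF398 (3.81) and RFX3 (a transcription factor of cilia genes; 3.74). Lower were DUSP15 (−4.16), MEFV (pyrin; −3.40), CLP1 (an RNA kinase; −3.40), ZNF598 (−3.35), ARAP3 (−3.19), ZNF747 (−3.13) and DNAI2 (an axonemal dynein; −3.09). The group with the lower signal had 3 of 4 arrays at the floor for MAP2, 2 for TRARG1 and DUSP15, and 1 for C21orf91, DMAP1, MEFV, ZNF598, ARAP3 and DNAI2, so that the sizes of these differences depend on the floor. On the myosin probe sets, MYH8 rose by 1.41 ± 0.21 (47558 ± 5358 against 18437 ± 5769, adjusted p = 3.4e-04) and MYH7 by 0.96 ± 0.22 (8384 against 4395, adjusted p = 0.00415). The other 6 did not pass; MYH13 differed by 0.42 ± 0.17 and MYH6 by 1.11 ± 0.46, while MYH3 (0.19 ± 0.84) and MYH1 (0.46 ± 0.34) changed sign under quantile normalization.

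Over all probe sets kept, the median log2 difference between layers and whole muscle was −0.18 on U133A and −0.21 on U133B. Quantile normalization moved it to 0.00 and −0.03, and a filter at the 75th percentile, which keeps brighter probe sets, to 0.15 and 0.26. List medians are therefore also given relative to the median of all probe sets kept, called all genes below. That median varied with intensity, and each list gene was represented by its brightest probe set. Such an offset therefore does not show that a list was higher than other probe sets of like intensity. Oxidative phosphorylation genes were higher in the layers in 46 of 65 members on U133A (median 0.27, or 0.45 above that of all genes), with 17 rising and 2 falling, counts that did not change when adjusted over the list alone; the median was −0.10 under quantile normalization. Camera gave adjusted p = 0.00754 and adjusted p = 0.664 with an estimated correlation, and adjusted p = 0.743 under quantile normalization, the highest over its alternatives. Alternatives reversed the direction of the list in 1 case and ended its call in 2 others. Among the latter was medial rectus replicate 2 left out (0.21, adjusted p = 0.0506 in camera). ATP5PB rose by 1.46 on U133A and differed by −0.27 on U133B, and COX6C fell by 1.31. Slow fibre genes were higher in 12 of 14 members (0.72, or 0.90 above all genes); 4 rose, among them TNNT1 by 1.45, and PLN, phospholamban, fell by 0.95. Of 13 fast fibre genes, 3 fell, ATP2A1 by 0.96, TNNC2 by 0.78 and MYL1 by 0.76, and 10 did not pass; MYL1 was at −0.18 under quantile normalization (adjusted p = 0.201, the highest over its alternatives). Camera gave no adjusted p under 0.05 for these 2 lists or for any other list on either array type. Calls under alternatives rest on the preset correlation, and the estimated one was not compared there. With the preset correlation, the slow list passed with array weights (0.90), 4 groups (0.72), no filter (0.62) and without global layer replicate 1 (0.97). The sarcomere list passed with no filter (0.28) and without global layer replicate 1 (0.34). With no filter and the preset correlation, the fatty acid (0.44) and glycolysis (0.42) lists on U133A passed too. So did the sarcomere, excitation-contraction, dystrophin and matrix lists on U133B. Also on U133B with the preset correlation, the excitation-contraction list passed with 4 groups (1.19) and without orbital layer replicate 1 (1.201) or 2 (1.16). The oxidative phosphorylation list there passed without orbital layer replicate 2 (0.67). On U133B, excitation-contraction coupling genes were higher in 7 of 7 members (1.41 above all genes, camera adjusted p = 0.0881), 3 rose, and 5 rose when adjusted over the list alone. Of the 3 that rose, CACNA2D1 (1.47) fell by 2.03 on U133A.

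Members of the other lists went both ways on U133A. For scale, 1964 of all 10533 probe sets tested rose and 3168 fell on U133A, and 2157 of 10547 rose and 2353 fell on U133B. This balance varied with intensity. With a filter at the 75th percentile, 59.5% (U133A) and 62.4% (U133B) of the probe sets that passed were higher in the layers. Of 23 glycolysis genes, 11 rose and 5 fell (median 0.64 above all genes), with FBP2 at 2.43 and PKM at −1.42. Of 22 fatty acid genes, 11 rose and 5 fell (0.66 above), with ECI1 at 1.72 and UCP2 at −1.58. Among 16 TCA cycle genes 6 rose and 4 fell, and among 15 sarcomere genes 7 rose and 2 fell; both medians changed sign under quantile normalization, as did those of the excitation-contraction, endothelial and hypoxia lists. Neuromuscular junction genes fell in 9 of 14 members and rose in 3 (−0.53 relative to all genes), with AGRN (agrin) at −1.35, ACHE (acetylcholinesterase) at −1.17 and RAPSN (rapsyn) at 1.61. Dystrophin complex genes rose in 8 of 14 members and fell in 3 (0.94 above), with LAMA2 at 1.66. Of 10 immune genes 5 fell and none rose (−0.63 relative to all genes), with CD74 at −1.31 and HLA-DRA at −1.30. Of 6 Schwann cell genes 3 fell, with GFAP at −1.95 and GAP43 at −1.67, and of 13 endothelial genes 3 fell. Of 28 matrix genes 6 rose and 8 fell, with FBN1 at 2.34 and COL1A1 at −1.57. Of 15 stress genes 6 rose and 3 fell (0.64 above), with GADD45B at 2.59 and JUNB at −0.91. Of 13 myogenic genes 3 rose and 4 fell, with MYOG at −2.03 and EYA1 at 1.31. On U133B, 5 of 9 matrix genes rose and 1 fell (1.18 above all genes), with COL3A1 at 2.36 and COL1A2 at 1.62. On U133A, probe sets of COL3A1 differed by −0.54, 0.30 and −0.17 without passing, and those of COL1A2 by 0.29 and 1.12. Of 5 endothelial genes on U133B, 2 rose and none fell (0.80 above), FLT1 (a receptor of vascular growth factors) by 1.76 and EMCN (endomucin) by 1.29. On U133A, FLT1 and EMCN differed by −0.26 and −0.35 without passing. Also on U133B, 5 of 10 sarcomere genes rose and 1 fell (1.32 above), and 7 of 15 oxidative phosphorylation genes rose and none fell (0.69 above). There 3 of 7 dystrophin complex genes rose and none fell (0.85 above), and 2 of 5 myogenic genes rose and none fell (0.54 above). Of 5 glycolysis genes on that array type, 3 rose and 1 fell (1.32 above). Among the genes counted as rising on U133B here, ALDOA, TTN, NCAM1, UTRN and SDHC had probe sets that fell on U133A, with values given below. The ACTB 3'/5' ratio was higher and the median intensity lower in the layers, as given above.

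In limma, 5132 of 10533 probe sets passed on U133A, 1964 higher and 3168 lower in the layers (38.3% higher), and 4510 of 10547 on U133B, 2157 higher and 2353 lower (47.8% higher). Under quantile normalization 4128 passed on U133A, 50.3% of them higher, with 3347 in common, and 3306 passed on U133B, 55.5% of them higher, with 2871 in common. On U133A 570 probe sets, and on U133B 653, were at least 2-fold apart in all 16 pairings. Several genes were measured with opposite directions by their probe sets on the 2 array types: MAP2 fell by 0.89 on U133A and rose by 3.96 on U133B, CD36 fell by 2.21 on U133A and rose by 1.55 on U133B, UTRN fell by 1.10 and rose by 1.99 (on U133A at −0.57 and adjusted p = 0.0923 under quantile normalization, the highest over its alternatives), and ENO3 differed by 0.46 and −2.16. ALDOA, TTN and NCAM1 fell by 0.41, 0.60 and 1.05 on U133A and rose by 1.73, 1.38 and 1.21 on U133B. SDHC rose by 1.77 on U133B, and its probe sets on U133A differed by −1.78 to 1.49. Other genes, such as ACAA2, UGP2, SNTB2 and MYLK, rose on both array types. Within an array type, other probe sets of ZNF398, ZNF598, PLN, UCP2, CD36 (U133A), FBN1 (U133A), TTN (U133B) and NCAM1 (U133B) went the opposite way to the value given, and those of FBN1 and NCAM1 passed.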

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

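Chosen only after the result was seen were the test of probe set pairs of 1 gene between layers and whole muscle and the test of the array with conflicting labels; the other tests below were set before. The check covered genes named for layers against whole muscle and the RNA and intensity measures of the arrays. By Dixon's test, 6 of 76 groups of 4 arrays held a value far from the other 3, all for genes. Chance flags about 1 in 20 groups, here 3.8 over genes and measures together. For RTN4IP1 and MAP2 the other 3 values were equal at the floor, so that any value above it was flagged. ZNF747 on U133A was at 216 on global layer replicate 1 and at 658 to 715 on the other layer arrays. MYH8 was at 39616 on global layer replicate 2 and at 49468 to 51354 on the others. MEFV was at 3975 on lateral rectus replicate 2 and at 2427 to 2658 on the other whole muscle arrays. On U133B, RTN4IP1 was at 331 and ZNF398 at 554 on lateral rectus replicate 1, where the other whole muscle arrays lay at the floor of 218 and at 409 to 423. MAP2 was at 1227 on medial rectus replicate 1 and at the floor on the others.

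Control probe sets for ribosomal RNA, which enter no comparison, gave a signal in the layers above that of whole muscle. The ratio of geometric means of the 18S control (n = 4 each) was 139 on U133A and 231 on U133B, but 4 and 3 of the 4 whole muscle arrays lay under the floor; with these raised to the floor, the 18S control was at least 89.4-fold and 159-fold higher in the layers. The 28S control, above the floor on all arrays, was 20.6-fold and 18.6-fold higher.

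Layers and whole muscle differed in 5132 probe sets on U133A and 4510 on U133B. Of the 35 splits of the 8 arrays, 1 on each array type, the real one, gave as many, and the highest of the others were 1 and 0. This argues against chance without excluding it, as 1 of 35 is the smallest share that such splits can give. The other splits mix layers with whole muscle, so a large difference between these lowers their counts. Unequal intensity distributions as the whole cause are argued against by quantile normalization, under which 73.3% or more of the count passed, but they stay open for a part of it, as 3347 of the 5132 and 2871 of the 4510 probe sets passed again and the share higher on U133A went from 38.3% to 50.3%. A dependence of signal on the place of a probe set in its transcript may account for part of the pattern, as may other reasons why probe sets of 1 gene disagree. The test used directions alone, without places, and cannot tell these apart. Of 1529 pairs of probe sets of 1 gene that both passed, 36.9% went in opposite directions, against 48.9% if directions were unrelated. The 95% Wilson interval, 34.5% to 39.3%, treats pairs as independent. Probe sets can recur in several pairs and all share the same arrays, so it may be too narrow. A difference between dissected layers and whole muscle, which the design names, stays open and cannot be told apart from the amplification of layer RNA, which covers the same arrays.

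The orbital and global layers differed in 39 probe sets on U133A. Of 101 same-gene pairs with an unadjusted p under 0.05, 3.96% went in opposite directions (95% Wilson interval 1.55% to 9.74%). The count used directions alone, without the places of probe sets in their transcripts. Probe sets at like places would go the same way under a dependence on place, so the low share cannot decide on it. Pairs with a larger p were not counted either, and such a dependence stays open. The ACTB ratio given above was higher on the orbital arrays, though the GAPDH ratio overlapped between the layers. Across array types, where the U133B probe sets needed no such p, fewer genes kept their direction, as given next. A layer difference in transcripts has in its favour that 63.6% of 143 genes with an unadjusted p under 0.05 on U133A went the same way on other probe sets of U133B (95% Wilson interval 55.5% to 71.1%), against 54.6% of the other 1186 genes. Both Wilson intervals treat pairs or genes as independent, though they share the same arrays, so they may be too narrow. The 2 array types may not be separate samples, however: 4 of 4 layer arrays on U133A matched the U133B array with the same title best over 100 shared probe sets, with 24 orderings possible. A biological difference between the layers, which the design names, stays among the open explanations.

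For orbital layer replicate 1 on U133A, whose title and source name conflict, the deviations of 77 genes correlated at r = 0.431 with the orbital minus global differences on U133B (across genes, which are not independent replicates; 95% bootstrap interval 0.193 to 0.619). The global arrays gave −0.424 and −0.454 and the other orbital array 0.555. Without the U133B array of the same title, which may hold the same RNA, the value was 0.302 (0.0678 to 0.495, 107 genes). Both intervals lie above 0, whereas global RNA was set to give a value below 0, so global RNA in this array is argued against, although neither interval lies wholly above the 0.2 set for an orbital array.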

How the results depend on the processing

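No test here was chosen after the results were seen; all alternatives were set before. Orbital against global layer, U133A: 23 probe sets passed under quantile normalization (22 of them among the 39), 0 in limma with no filter (1607 with an unadjusted p under 0.05; 3034 of the 22215 probe sets tested were flat at the floor), 12 without a variance trend, and 68 to 144 with 1 array left out. Those 2-fold apart in all pairings were 320 with no filter, 60 with a filter at the 75th percentile and 232 to 467 with 1 array left out, where fewer pairings are needed. With the replicate number as a block, 92 passed on U133A and 26 on U133B. The sarcomere list on U133B passed with the preset correlation (median 0.01, with a negative mean in the main fit, as given above). The labels do not say that a number marks an animal, and deviations of the 2 pairs correlated at 0.256 and 0.132 across probe sets. In simulated tables, 9.34% to 12.6% (U133A) and 7.72% to 13.1% (U133B) of block calls were false. On U133B, 0 passed under quantile normalization (760 with an unadjusted p under 0.05 in limma), a floor at the 5th percentile (733), no filter (1626) or no variance trend (674), 19 with a floor at the 40th percentile, 23 with a filter at the 75th percentile, 10 with all 4 groups in one fit, and 0 to 28 with 1 array left out (8 and 28 without global layer replicates 1 and 2, 1 and 0 without orbital layer replicates 1 and 2, the last with 567 under 0.05); those 2-fold apart were 572, 49 and 474 to 593 with no filter, the 75th percentile and 1 array left out. Medial against lateral rectus, U133A: 7 passed with a filter at the 75th percentile and 0 to 9 with 1 array left out (9 and 1 without medial rectus replicates 1 and 2); those 2-fold apart were 107 with a floor at the 40th percentile, 382 with no filter, 10 at the 75th percentile and 332 to 491 with 1 array left out, and on U133B 703, 19 and 741 to 1230 for the last 3. Layers against whole muscle: 2513 (U133A) and 2799 (U133B) passed with a filter at the 75th percentile, which tests fewer probe sets. Of these, 59.5% and 62.4% were higher in the layers. The oxidative phosphorylation list on U133A turned to −0.10 under quantile normalization. Beyond the fewer probe sets or arrays that an alternative leaves, the cause was not tested. Between the layers on U133A, 966 values of named genes under alternatives kept their side of the threshold, 40 lost the call and 23 gained one. Between layers and whole muscle on U133A they were 1198, 46 and 9. The values that kept their side include genes without a call in the main fit that stayed without one, whatever their direction. These counts therefore do not measure how stable the calls were. A fit with 1 array in a group assumes that this array varies like the others. Signal near the floor limits all of this: 24.8% of layer values and 15.2% of whole muscle values on U133A were raised to it. The replicate term was not run for the recti, whose titles do not number every array.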

Other observations

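No test in this part was chosen after its result was seen, and the genes follow the rule for named genes. Some genes outside the largest differences also varied with the layers without passing in limma. MYH7B, a myosin heavy chain of slow type, was at 13855 in the orbital and 2261 in the global layer on U133B (log2 difference 2.67 ± 0.34, adjusted p = 0.0617). MYH15, another slow-type myosin heavy chain, was higher by 1.52. MYOM3, an M-band protein, differed by −1.82 and NOS1, the neuronal nitric oxide synthase, by −1.85, both on U133B, while NOS1 on U133A differed by −0.28. THBS4, a matrix protein of muscle and tendon, was higher by 1.77 and FMOD, fibromodulin, by 1.09. TEK, the angiopoietin receptor of endothelium, differed by −1.49 (another probe set went the opposite way), FABP4, a fatty acid binding protein of fat and capillaries, by −1.74, and CD36, a fatty acid transporter, by −1.29 on U133B. HBB differed by 0.09 between the layers.

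Layers and whole muscle differed in further genes past the threshold. In whole muscle AHSP, a chaperone of alpha-globin, and ALAS2, the haem synthesis enzyme of red cells, were higher, with log2 differences of −1.90 and −2.04 for layers minus whole muscle. CD79A and MS4A1, genes of B cells, were also lower in the layers (−1.02 and −0.93), but CD79A did not pass under quantile normalization (−0.52, adjusted p = 0.0856, the highest over its alternatives). MYH11, the smooth muscle myosin heavy chain, rose by 2.40 in the layers while NOTCH3, a receptor of pericytes, fell by 1.10 and did not pass under quantile normalization (−0.61, adjusted p = 0.0609, the highest over its alternatives).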
